A study of Rattus norvegicus with 6 samples.

How the data were processed

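Rat primary cortical cells, a mixed culture of neurons and other cells of the cerebral cortex, were transfected with an expression vector for Math2 or with a control vector. Math2 is an older name of Neurod6, a basic helix-loop-helix (bHLH) transcription factor of neurons. Per the labels' protocols, each dish also received a vector for a truncated low-affinity nerve growth factor receptor, a surface tag by which transfected cells were pulled out magnetically 24 h later. Total RNA of the selected cells went through 2 cycles of amplification and labelling before hybridization to Affymetrix Rat Genome 230 2.0 arrays. The titles name 3 control and 3 Math2 samples. The labels do not say whether these came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

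The deposited table holds 1 intensity per probe set and array, on a linear scale. The submitters' processing notes name MAS5, with no version, and its settings are not given in the sources used here. MAS5 combines the probes of a probe set into 1 signal after subtracting mismatch and background intensity. The mean of the deposited intensity after removal of the highest and lowest 2% of probe sets was 500 on every array, so the values were used as already scaled. Scaling of this kind equalizes the bulk of the signals and leaves room for differences among the brightest. The table holds no detection calls, so whether a dim probe set was above background is unknown, and folds from signals near or below the array medians of 102 to 120 are uncertain. The number of arrays, 3 per group, limits the precision.

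Of 31099 probe sets, 57 control probe sets were kept out of the tests and used only to describe the arrays. The platform annotation, which is several years old, gave 1 gene symbol to 20826 probe sets, several to 436 and none to 9780. Of the single symbols, 20764 were matched by gene number to RefSeq genes of the GRCr8 assembly, and 0 changed. The array names no genome build and no genome was used, so no coordinates are given.

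Signals were transformed to log2(signal + 7.42), where the pseudocount is the 10th percentile of all positive values. A log2 difference is on this scale, which understates the change of dim probe sets. A fold of a probe set is 2 to the power of this difference, and a fold of an array measure is the ratio of geometric means, so neither equals the ratio of the mean signals printed beside it. Probe sets with a mean log2 value at or above the 40th percentile, 6.07, were tested, which left 18625 with 10417 gene symbols. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. A size rule without a test counted probe sets with at least a 2-fold difference and no overlap between the groups. For single values, an exact two-sided permutation test of 3 against 3 arrays was run, whose smallest possible p is 0.1.

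The replicate numbers of the titles were checked for pairing. Deviations from the group means correlated at 0.326, 0.476 and 0.372 across probe sets for the control and Math2 arrays that share number 1, 2 and 3, and each lay above the limit of 0.1 set for pairing. Of the 6 combinations of unlike number, control 1 with Math2 3 also lay above it, at 0.104, and the others ranged from -0.46 to -0.0401. Deviations within a group cancel out, so high values for like numbers push those for unlike numbers down. The low values for unlike numbers are thus no separate support for pairing. Genes are not independent replicates, so this is a description. The numbers were therefore treated as pairing the samples, on the basis of the data, since the labels do not say what a number stands for. The fit without the number as a block was the planned main one. The exact permutation test also leaves the numbers out, so its p takes no account of pairing. The value with the replicate block is printed beside a result where it changes the call.

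The groups, tests and thresholds, 24 gene lists and the rule for naming genes were fixed before the data were examined. Named are every probe set of Neurod6, Plppr4 and Srgn, up to 4 members per list with the smallest p, and the 12 higher and 12 lower single-symbol probe sets with the smallest unadjusted p. The last part of the rule applied because fewer than 24 probe sets passed the threshold. For lists, a gene was represented by its brightest probe set on average. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, with an estimated correlation as an alternative and fry beside it, and adjusted over the 24 lists. Members were also adjusted over the list alone.

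The fit was tested on simulated data of 18625 probe sets, 200 of them changed. With SDs shrunken by eBayes, the fit of Math2 against control recovered 15% of 2-fold and 86% of 4-fold changes with 7 false calls, and the fit with the replicate block recovered 47% and 95% with 9 false calls. With each probe set's own SD, which comes from few degrees of freedom, the shares were 1% and 52% with 2 false calls, and 0% and 0% with the block. The recovery thus rests on which spread is assumed, and the shrunken SDs were taken up after the own SDs had given low shares. Values for the fit without the block were drawn without pairing by number. The real arrays showed such pairing, so these shares may not describe that fit. In a simulation of 24 lists, camera called the 1 list shifted by a log2 of 1 over 20 members and 0 of the others. That shift is larger than the median of any list in the real data, so the simulation says little about small shifts. Its values were drawn independently for each probe set, so it says nothing about false calls where genes of a list move together.

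Alternatives were other pseudocounts, filters and normalizations, the replicate block, other variance models, array weights, each array left out in turn, and another representation of genes. Added after the data were seen were the block together with quantile normalization, with median centring, with an estimated correlation or without each numbered pair, and the Gapdh 3' to 5' ratio as a covariate.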

Results

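Gene expression was measured in rat primary cortical cells transfected with Math2 (Neurod6) or with a control vector and selected through a co-transfected surface tag 24 h later. There were 3 control and 3 Math2 arrays with 31099 probe sets each. The series title names Prg1, plasticity-related gene 1, as regulated by Math2, and the stated purpose was to find genes that Math2 acts on. Median signals ran from 102 to 120 per array. Pearson correlations of log2 signals across probe sets were 0.91 to 0.95 within groups and 0.918 to 0.962 between groups, and these ranges overlapped.

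The arrays differed in technical measures as well. Hybridization spike-ins, transcripts added in fixed amounts before hybridization, had a geometric mean signal of 2312 ± 365 in the control arrays and 4897 ± 1627 in the Math2 arrays (SD, n = 3), and every Math2 array lay above every control array (exact permutation p = 0.1, the smallest possible). The brightest 1% of tested probe sets, 187 in number, had a median log2 difference of 0.43, and 186 of them were higher on the Math2 arrays. Over all tested probe sets the median was -0.031. The Gapdh 3' to 5' ratio, a measure of how complete the labelled transcripts were, was 13.8, 3.74 and 5.04 on control arrays 1, 2 and 3, and 8.48, 6 and 8.14 on Math2 arrays 1, 2 and 3.

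**Figure D1:**
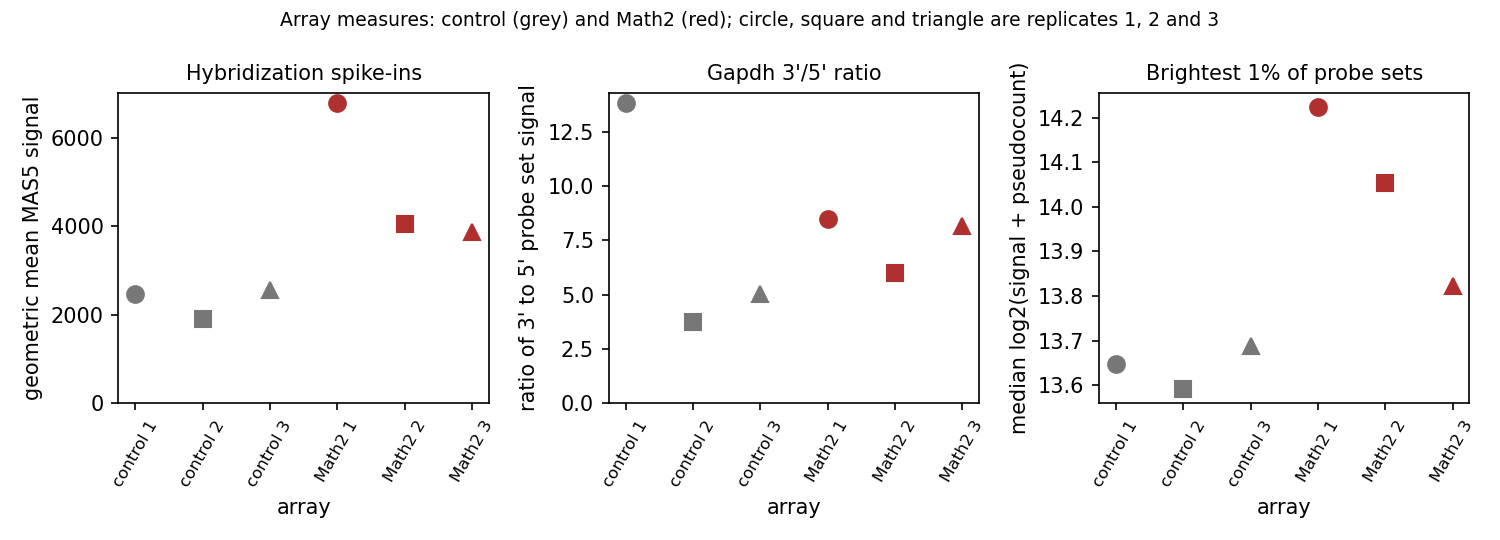
Each point is 1 array, grey for control and red for Math2, with circles, squares and triangles for replicates 1, 2 and 3. The left panel plots the geometric mean signal of the hybridization spike-ins, the middle panel the Gapdh 3' to 5' signal ratio, and the right panel the median log2 signal of the brightest 1% of probe sets on an axis that does not start at 0. Spike-ins and brightest probe sets were higher on all Math2 arrays, and the Gapdh ratios of the groups overlapped.

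Plppr4, the current symbol of plasticity-related gene 1 and a membrane protein of neurons, was the title gene. The brighter of its 2 probe sets had a signal of 224 ± 62.9 in the control arrays and 930 ± 217 in the Math2 arrays (SD, n = 3), a log2 difference of 2.03 (SE 0.316), or 4.09-fold on the log2(signal + pseudocount) scale. The difference was present in 3 of 3 numbered pairs and the groups did not overlap (exact permutation p = 0.1, the smallest possible). In limma it did not pass over all probe sets (adjusted p = 0.562), and it passed with the replicate block (adjusted p = 0.0151). Over all alternatives its adjusted p ran from 7.84e-05 to 1.00, and it passed in every setting with the block and in none without it. The dimmer Plppr4 probe set measured 77.7 ± 5.16 and 213 ± 75.4, from a control level below every array median, with a log2 difference of 1.32 (SE 0.351) that did not pass in limma either way (adjusted p = 1.00 without and 0.297 with the block).

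Of the plasticity-related gene family, 4 of 5 members were measured. Plppr4 alone passed when adjusted over the list alone (limma adjusted p = 2.42e-04). The series title names this gene, and the arrays were made to find such genes. It may have been chosen from these same arrays, so that pass is no independent support. Plppr3 had a log2 difference of 0.28, Plppr5 of -0.18 and Plppr2 of -0.035, and the last turned to 0.026 with quantile normalization. As a set the family had a median of 0.12 and did not pass in camera (adjusted p = 0.0643, or 0.578 with an estimated correlation), and it passed with quantile normalization (adjusted p = 0.0208) and with median centring (adjusted p = 0.0495). It also passed without control array 3 (median 0.24) and without Math2 array 1 (0.23), whereas the median was 0.0096 without Math2 array 3 and 0.040 without control array 2, and over all alternatives its adjusted p ran from 0.00649 to 0.801. Plppr4 is among the 4 measured members and had by far the largest difference of them. The camera passes of the family are therefore no independent support either.

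Neurod6, the transfected gene, showed no difference that passed a test (exact permutation p = 1). Its probe set had signals of 386, 207 and 973 on control arrays 1, 2 and 3 and of 312, 167 and 1546 on Math2 arrays 1, 2 and 3, with a log2 difference of 0.021 (SE 0.745) that was above 0 in 1 of 3 pairs. The labels do not give the transfected sequence or its species, so this probe set may lie outside it and checks nothing about the labels. Srgn, the proteoglycan serglycin, has also carried the symbol Prg1; it measured 154 ± 52.2 and 167 ± 81.5 (SD, n = 3), a log2 difference of 0.035 (SE 0.434). For both, the sign depended on which arrays were used.

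**Figure D2:**
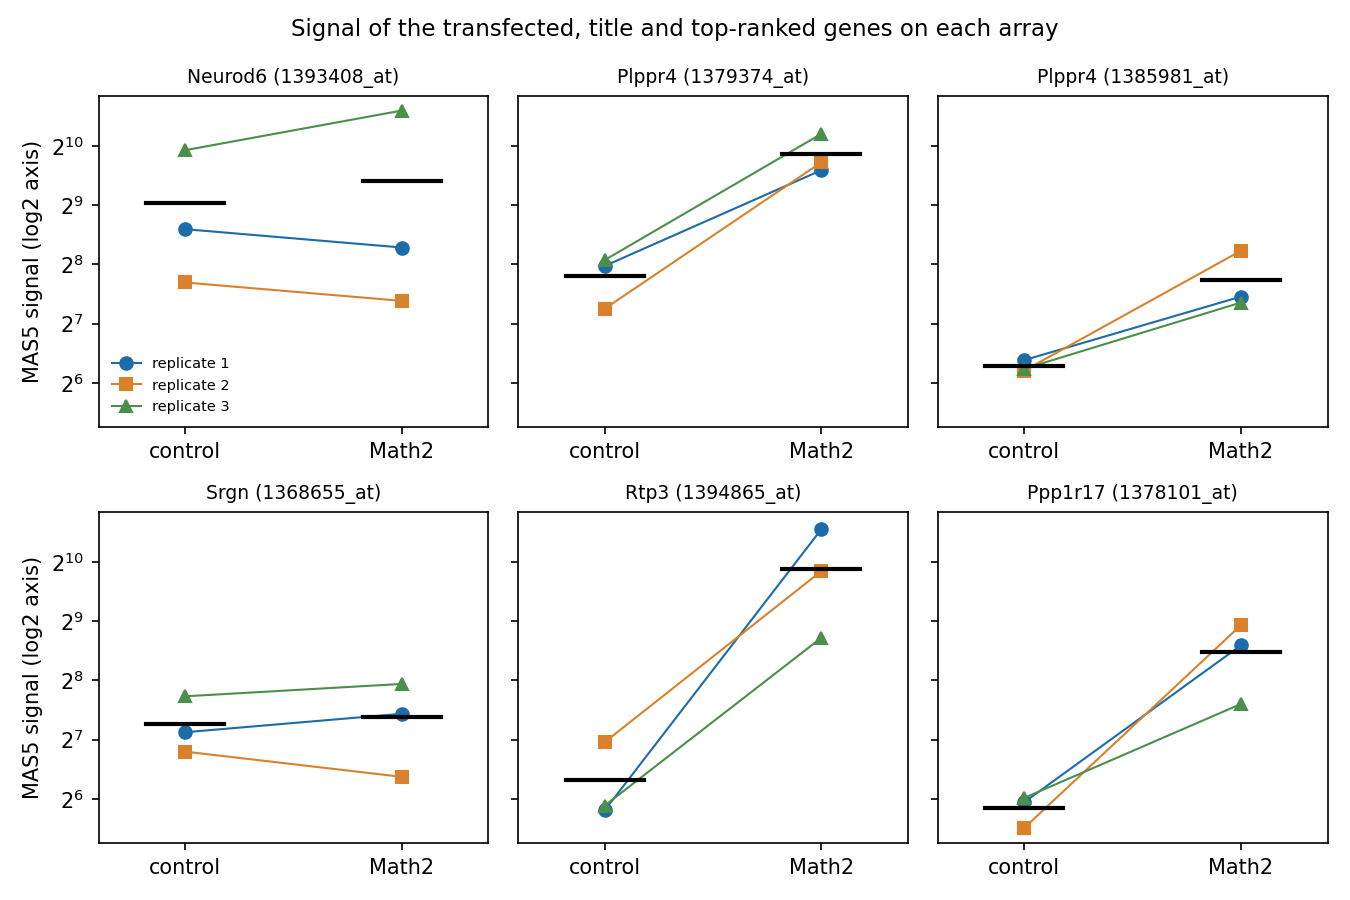
MAS5 signals on a log2 axis for 6 probe sets, with control and Math2 arrays on the horizontal axis, lines joining arrays of the same replicate number and black bars at the group means. The Math2 arrays lay above the control arrays for both Plppr4 probe sets, Rtp3 and Ppp1r17, and the groups overlapped for Neurod6 and Srgn.

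Across 18625 tested probe sets, limma called 0 higher and 0 lower without the block, with a smallest adjusted p of 0.492. At an unadjusted p under 0.05, 326 were higher and 268 lower, against 931 for chance alone in independent samples. That number is no reference for this fit where samples pair by number. With the replicate block 3 rose and 0 fell, and 704 and 731 lay under the unadjusted 0.05. The 3 were Rtp3, Plppr4 and probe set 1389584_at, which has no gene symbol here and was chosen after its values were seen. Rtp3, of the receptor transporter protein family, measured 79.9 ± 38.6 and 945 ± 538 (SD, n = 3), a 10.2-fold difference on the same scale, from a control level below the array median (block adjusted p = 0.00763; 7.34e-15 to 1.00 over all alternatives). Probe set 1389584_at measured 683 ± 164 and 2533 ± 1131, a 3.53-fold difference on that scale (block adjusted p = 0.0151). All of these were higher in 3 of 3 pairs.

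By size alone, 69 probe sets were at least 2-fold higher and 61 at least 2-fold lower in the Math2 arrays without overlap between the groups. Overlap was absent for 8% of tested probe sets, against 10% by chance for 6 exchangeable arrays, which is no reference for samples that pair by number.

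The next probe sets by p did not pass in limma either without or with the block. On the higher side, Ppp1r17, an inhibitor of protein phosphatases, had a control level of 57.4 ± 10.3 (SD, n = 3), below every array median. The size of its difference is therefore uncertain. Ppp1r17 had a log2 difference of 2.40 (SE 0.396, limma adjusted p = 0.0897 with the block). It was called with the block and quantile normalization (adjusted p = 0.0214; 0.00497 to 1.00 over all alternatives). Cdkn1c, an inhibitor of cyclin-dependent kinases, measured 3796 ± 511 and 8073 ± 1176 (SD, n = 3), and Elavl2, an RNA-binding protein of neurons, measured 2337 ± 378 and 4773 ± 439, with log2 differences of 1.08 (SE 0.201) and 1.04 (SE 0.209). Id2, an antagonist of bHLH factors, measured 7196 ± 1050 and 15348 ± 4370 (log2 difference 1.07), and Ctnnb1, beta-catenin, 7119 ± 668 and 17091 ± 8508 (1.15). These last signals lie among the bright probe sets, and with quantile normalization their log2 differences were 0.81 and 0.84. Another, brighter Ctnnb1 probe set had a log2 difference of 0.69, which was 0.20 with quantile normalization. Bola2 and Tmem178a had log2 differences of 1.07 and 1.12. Also dim in the control arrays were Pdgfrb (51.7 ± 13.2), a platelet-derived growth factor receptor, the neuropeptide gene Gal (47.8 ± 21.4) and the cytokine gene Tnf (36.3 ± 8.53), with log2 differences of 1.77, 2.15 and 2.30.

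On the lower side, Ncoa3, a nuclear receptor coactivator, measured 204 ± 44.9 and 61.1 ± 21.0 (SD, n = 3), and Ntng1, the axonal membrane protein netrin G1, 321 ± 26.5 and 129 ± 19.8, with log2 differences of -1.65 (SE 0.366) and -1.28 (SE 0.297). The sodium channel gene Scn7a had a log2 difference of -1.73, the chemokine gene Cx3cl1 of -1.45, the endoplasmic reticulum stress factor Atf6b of -1.44 and the GTPase gene Rab15 of -2.07. Gpc4, a cell surface glypican, was the brightest of the group at 8704 ± 2151 and 4550 ± 1663, with a log2 difference of -0.97 (SE 0.296; block adjusted p = 0.12). It was called lower with the block and quantile normalization (adjusted p = 0.0047; up to 1.00 over all alternatives). Dolpp1, LOC102549521, Vwa3a, Fat4 and Osbpl6 had log2 differences of -1.05, -1.53, -2.12, -1.02 and -0.95. All 12 were lower in 3 of 3 pairs except Vwa3a, which was higher in 1. In the Math2 arrays Ncoa3, Scn7a (mean 53.2), Atf6b (58), Rab15 (36.3) and Vwa3a (55.3) were dim. These means lay below every array median, so the sizes of their differences are uncertain.

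Of 24 gene lists, 2 were called by camera, and with an estimated correlation 0 were called. No list passed with fry (smallest adjusted p = 0.873, or 0.571 with the block). Other groupings of the same 6 arrays called up to 13 lists, so a camera call here does not set the real grouping apart.

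Interferon response genes, induced by antiviral signalling, rose as a set. Of 24 measured, 19 were higher and 5 lower, with a median log2 difference of 0.24 (camera adjusted p = 1.19e-04, and adjusted p = 0.882 with an estimated correlation). Cxcl10, an interferon-induced chemokine, measured 1383 ± 663 and 2917 ± 652 (SD, n = 3), and Rsad2, an antiviral enzyme, 7049 ± 2864 and 13890 ± 5429, with log2 differences of 1.16 and 1.00. The 2'-5' oligoadenylate synthetase family genes Oasl and Oas1b had differences of 0.95 and 1.16. Over the list alone, 0 members passed in limma, and 5 passed with the replicate block. The list was no longer called without control array 3 (median 0.068, adjusted p = 0.184), without Math2 array 1 (0.12, adjusted p = 0.0526) or, with the block, without numbered pair 1 (0.042, adjusted p = 0.133). Its median was 0.59 without control array 2 and 0.53 without Math2 array 3. Over all alternatives its adjusted p ran from 8.56e-14 to 0.882. Spike-ins and the brightest probe sets were higher on the same arrays, and the list's median was 0.17 with quantile normalization (adjusted p = 8.16e-04).

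Fibroblast and meningeal markers fell as a set, with 14 of 15 measured members lower and a median log2 difference of -0.33 (camera adjusted p = 0.00644, and adjusted p = 0.578 with an estimated correlation). Aldh1a2, a retinoic acid synthesis enzyme, had a difference of -0.98, the fibrillin gene Fbn1 of -0.45, the collagen gene Col5a1 of -0.48 and the matrix protein gene Mgp of -0.55. Over the list alone 0 members passed in limma. The list was not called without Math2 array 3 (median -0.24, adjusted p = 0.0716), without a filter (-0.21, adjusted p = 0.119), with the stricter filter (-0.25, adjusted p = 0.0518) or, with the block, without numbered pair 3 (-0.12, adjusted p = 0.265). Its median was -0.21 without control array 3 and -0.45 without control array 2, and both settings called it. Over all alternatives its adjusted p ran from 0.00113 to 0.801.

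The other lists for cell types did not pass in camera. Excitatory cortical neuron markers had a median of 0.28 over 15 genes (8 higher, 7 lower; adjusted p = 0.109), with Fezf2 at 1.11, Foxp2 at 0.90, Nrgn at 0.79 and Eomes at 0.60. With quantile normalization that median was 0.047, and without control array 2 it was -0.019. The list was called without control array 3 (0.26), without Math2 array 2 (0.46) and, with the block, without numbered pair 1 (0.059; adjusted p = 0.0189, and up to 0.831 over all alternatives). Inhibitory neuron markers had a median of -0.13 (2 higher, 9 lower), with Dlx5 at -0.55 and Reln at -0.47. Pan-neuronal markers had a median of 0.056 (11 higher, 8 lower), with Rbfox3 at 1.18 and Syp at -0.48, and were called higher without control array 3 (0.41) or Math2 array 1 (0.25) and lower without Math2 array 3 (-0.47). With the block they were also called without numbered pair 1 (0.0094; adjusted p = 0.0225, and 0.0148 to 0.993 over all alternatives). Astrocyte markers had a median of -0.045 (7 higher, 9 lower). Among them Fgfr3 measured 5107 ± 407 and 3423 ± 95.1 (SD, n = 3), a difference of -0.57, and the bright gene Vim had 0.51, which became -0.032 with quantile normalization. That setting called the astrocyte list lower (median -0.12, adjusted p = 0.0323; 0.0285 to 0.993 over all alternatives). Medians were -0.019 for oligodendrocyte lineage markers (Bcas1 0.43, Cldn11 -0.49), -0.027 for microglia and macrophage markers (Ctss 0.36, Fcer1g -0.31), 0.01 for endothelial and mural cell markers, which was -0.026 with quantile normalization, and -0.0044 for neural progenitor markers (Notch1 -0.61, Hes5 0.75). Only 6 of 22 microglial and 8 of 20 oligodendrocyte markers were tested past the filter. Control means of Fezf2 (44.1), Hes5 (46.6) and Rbfox3 (89.0) lay below every array median, so the sizes of their differences are uncertain. Pdgfrb was the only member of the endothelial and mural list to pass when adjusted over the list alone (limma adjusted p = 0.01).

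Among regulators of neuronal differentiation, the Notch pathway and bHLH antagonists had a median log2 difference of 0.18 (12 of 18 higher; camera adjusted p = 0.109). Id2 passed when adjusted over the list alone (limma adjusted p = 0.0112), and with the block the Notch ligand gene Dll4 passed too, with a difference of 1.34 (list adjusted p = 0.0164). Hes6 had 0.55 and Notch1 -0.61. Neuronal bHLH factors and partners had a median of 0.041 (6 of 10 higher, camera adjusted p = 0.511). Tcf4, a partner of neuronal bHLH factors, measured 9317 ± 1099 and 14272 ± 3099 (SD, n = 3). Its log2 difference was 0.60, or 0.31 with quantile normalization. Neurod2 had 0.78, Neurod1 0.49 and Myt1l -1.08. Control means of Dll4 (66.1) and Neurod2 (83.2) lay below every array median, so the sizes of their differences are uncertain.

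Lists of neuronal function did not pass either. Medians were -0.13 for synapse and glutamate receptor genes (6 higher, 13 lower; Dlg4 -0.56, Gria2 -0.39), -0.049 for axon guidance and neurite outgrowth genes (15 higher, 17 lower; Ncam1 -0.63, Sema3e -0.72, Epha5 -1.37, Marcks 0.39) and 0.028 for ion channel genes (9 higher, 8 lower; Kcna2 0.91, Kcnj3 0.91, Hcn2 -0.68). Activity-regulated and neurotrophin genes had a median of 0.12 (13 of 20 higher; adjusted p = 0.199), with the immediate early genes Egr1 at 0.57 and Ier2 at 0.55. Lipid phosphate and LPA signalling genes, the pathway nearest to plasticity-related gene 1, had a median of -0.17 (10 of 15 lower; adjusted p = 0.199), with Dgkb at -0.89 and S1pr3 at -0.51. Without Math2 array 2 that median was -0.38, and without control array 1 it was -0.26.

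Inflammatory cytokine and acute response genes had a median of -0.30 (5 higher, 13 lower; camera adjusted p = 0.774), with members on both sides. Without control array 2 that median was 0.076. The list was called without control array 3 (-0.30, adjusted p = 0.0234) and, with the block, without numbered pair 1 (-0.45, adjusted p = 6.83e-04), against up to 0.993 over all alternatives. Tnf passed over the list alone (limma adjusted p = 0.0338), at 36.3 ± 8.53 and 268 ± 251 (SD, n = 3). Its signals on Math2 arrays 1, 2 and 3 were 558, 131 and 115, so array 1 carried much of that mean. With the replicate block Cxcl1, Ccl4 and Ccl20 passed over the list alone as well, with log2 differences of -1.38, 1.61 and -1.06 and list adjusted p of 0.00623, 0.0108 and 0.0124. The remaining lists were not called. Medians were -0.11 for cell cycle genes (Plk1 -0.54), -0.044 for heat shock and unfolded protein response genes (Trib3 0.75), -0.013 for apoptosis and p53 response genes (Bid -0.52) and -0.084 for antioxidant genes. Txn1, thioredoxin, passed over the antioxidant list alone with the block (0.64, or 0.054 with quantile normalization; list adjusted p = 0.028). Mitochondrial respiratory chain and biogenesis genes had a median of 0.18 (19 of 33 higher; adjusted p = 0.094; Cox7b 0.77), which was 0.048 with quantile normalization, 0.0049 without control array 1 and 0.019 without Math2 array 2. For the oligodendrocyte, microglia, progenitor, heat shock and antioxidant lists the median was below 0 while camera's direction was up.

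**Figure D3:**
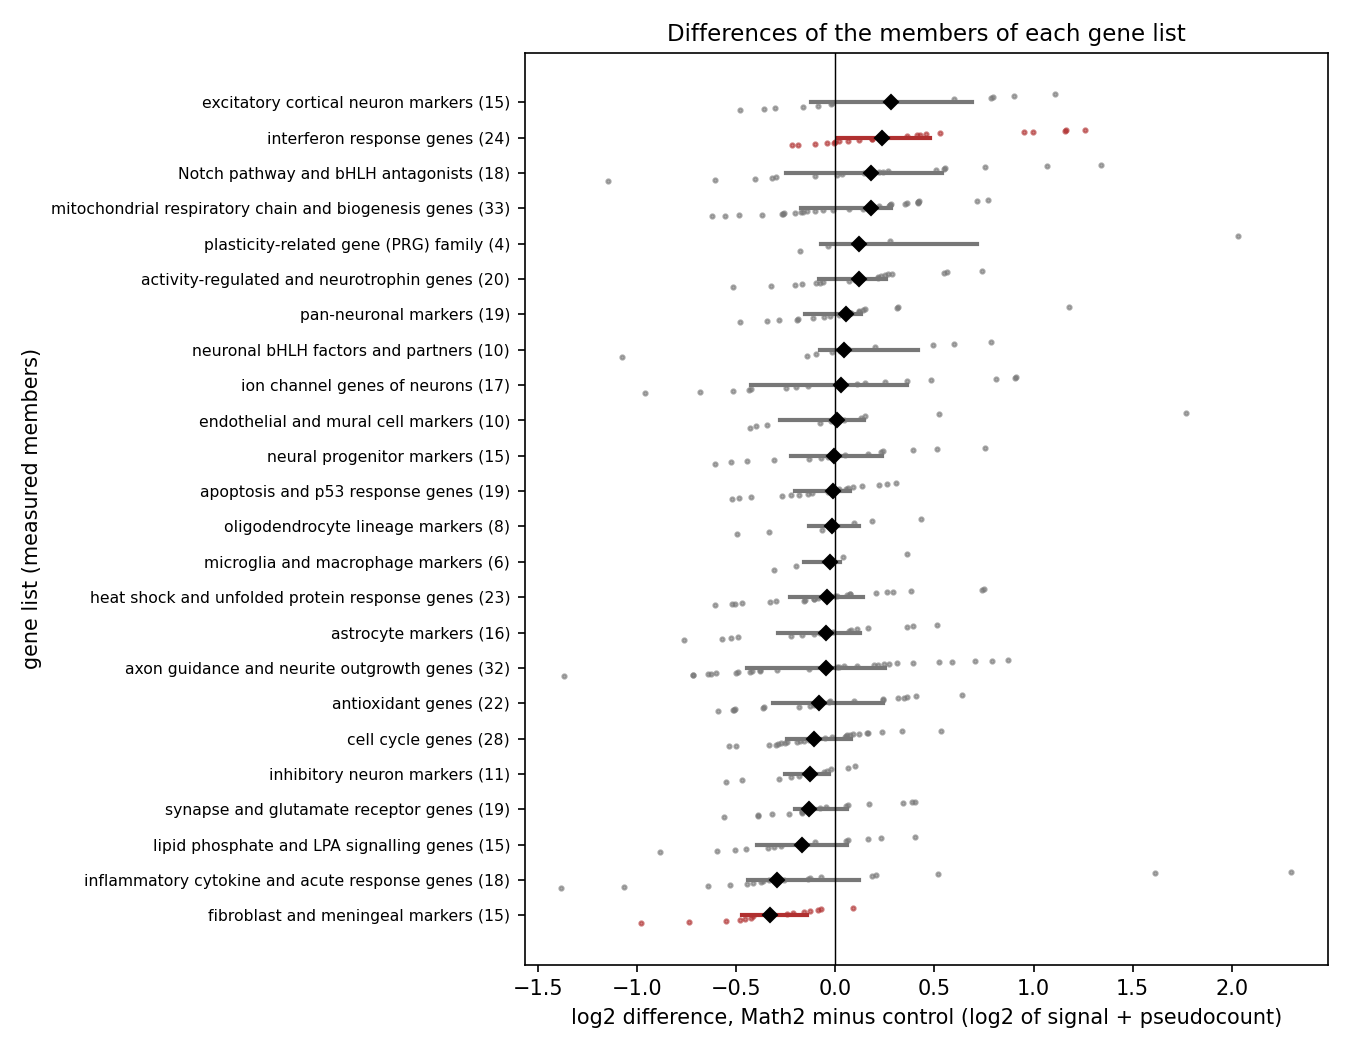
Log2 differences, Math2 minus control, of the measured members of each gene list (dots), with the number measured in parentheses, the median as a diamond and the line from the 25th to the 75th percentile. The 2 lists called by camera are in red, with medians of 0.24 for interferon response genes and -0.33 for fibroblast and meningeal markers.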

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

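The tests of abundant transcripts by spike-in order and by RNA integrity were chosen after the result was seen. Hybridization spike-ins were 2.07-fold higher on the Math2 arrays by the ratio of geometric means (arithmetic means 4897 ± 1627 against 2312 ± 365, SD, n = 3), a signal from control probe sets that lay above all control arrays. The 5S ribosomal RNA probe set was 1.78-fold higher by the same ratio, with arithmetic means of 639 ± 233 against 348 ± 66.7 (SD, n = 3), also without overlap. Spike-ins added before amplification had a 2.70-fold higher geometric mean, higher in 3 of 3 pairs but with overlap between the groups.

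These go with higher signals of abundant transcripts, a median log2 difference of 0.43 over the brightest 1% of probe sets. The actin 3' to 5' ratio was higher in 2 of 3 pairs and lower in the other. The brightest probe sets were higher in all 3 pairs, by 0.683, 0.475 and 0.188. The pair with the lower ratio rests on control array 1, which had the highest ratio, 22.7. RNA integrity as the cause therefore stays open. Scaling that depends on intensity may also be the cause. The numbered pairs stood in the same order by spike-in difference as by the difference of the brightest probe sets, 3 of 3. Chance gives that order often, so the test decides nothing. Ribosomal protein probe sets, a class noticed in these data, had a median of 0.48 (77 of 86 higher), above all of 10000 random lists matched on mean signal (percentile 100; central 95% from 0.26 to 0.38), but a class chosen from the same data decides nothing about scaling. Their median was 0.067 with quantile normalization, which forces the brightest signals to be alike, so scaling and an effect of Math2 both stay open.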

How the results depend on the processing

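The block with quantile normalization, with median centring, with an estimated correlation or without a numbered pair, and the Gapdh covariate, were chosen after the data were seen. Of 113 named genes, 2377 comparisons with another setting kept direction and side of the threshold, 36 came past it and 37 changed direction; of 24 lists, 440 kept both, 26 came past it, 11 fell short and 74 changed direction. The brighter Plppr4 probe set stayed between 1.78 and 2.26. The replicate block raised the count of higher probe sets to 3 and took Plppr4 past the threshold at an unchanged 2.03. It changed no camera call; other calls it changed are those adjusted over the list alone in the report. With the block, quantile normalization gave 4 higher and 1 lower, and median centring 4 higher and 1 lower (1387010_s_at, which has no gene symbol here and was named after its values were seen). Without a numbered pair, on 1 residual degree of freedom, the block fit gave 4 to 51 higher and 0 to 63 lower; Rtp3, Plppr4 and 1389584_at were called each time. The 2-fold count of 130 became 62 with the higher pseudocount, 837 without a filter, 40 with the stricter filter and 171 to 425 without 1 array, where chance non-overlap is larger by construction. Lists called were 1 without a filter, 1 with the stricter filter, 4 with quantile normalization (4 with the block too), 0 with an estimated correlation (0 with the block too), 2 to 6 without 1 array and 2 to 5 without 1 pair. Signal over background is unknown without detection calls, which limits dim genes. The calls gained without 1 array were the plasticity-related gene family without control 3 or Math2 1, bHLH factors and excitatory markers without control 3 or Math2 2, Notch and inhibitory markers without control 2, mitochondrial genes without control 2 or Math2 3, pan-neuronal markers without control 3, Math2 1 or, lower, Math2 3, inflammatory genes without control 3, and activity-regulated and cell cycle genes without Math2 1. With the block, the plasticity-related gene family, excitatory, pan-neuronal and inflammatory lists were gained without pair 1, and the mitochondrial list without pair 3. The Gapdh covariate added the mitochondrial list (0.19). The cause was not tested.

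Log2 differences that changed sign without 1 array or pair ranged as follows: Srgn -0.29 to 0.45 (block -0.096 to 0.25), Neurod6 -0.88 to 0.69 (block -0.30 to 0.18), Plppr5 -0.57 to 0.15, Plppr2 -0.31 to 0.27, Neurod1 -0.084 to 1.19, Maf -0.73 to 0.41, Cck -0.47 to 0.15, Elavl3 -0.021 to 0.69, Gria2 -0.73 to 0.15, Syt4 -0.20 to 0.79, Vgf -0.96 to 0.039, Bcas1 -0.0090 to 0.77, Pdgfra -0.83 to 0.021, Ctss -0.22 to 0.79, Apoe -0.72 to 0.28 and Lyz2 -0.27 to 0.29. With quantile normalization, with or without the block, Plppr2 was 0.026, Vim -0.032, Fabp7 -0.15, Hspd1 -0.11 and Ccng1 -0.0045. With the Gapdh covariate Srgn was -0.0094, Neurod6 -0.063 and Plppr2 0.025. With array weights Neurod6 was -0.12 and Lyz2 -0.051.

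List medians that changed sign ranged, without 1 array or pair, from -0.28 to 0.62 for neuronal bHLH factors, -0.059 to 0.26 for Notch, -0.019 to 0.46 for excitatory, -0.40 to 0.019 for inhibitory and -0.47 to 0.41 for pan-neuronal markers, -0.36 to 0.15 for synapse, -0.24 to 0.073 for axon guidance and -0.052 to 0.19 for activity-regulated genes, -0.33 to 0.24 for astrocyte, -0.26 to 0.15 for oligodendrocyte, -0.30 to 0.24 for microglia, -0.15 to 0.31 for endothelial and -0.092 to 0.10 for progenitor markers, -0.19 to 0.12 for cell cycle, -0.45 to 0.076 for inflammatory, -0.11 to 0.036 for heat shock, -0.14 to 0.096 for apoptosis, -0.22 to 0.13 for antioxidant and -0.16 to 0.14 for ion channel genes. The pan-neuronal list was called in opposite directions without Math2 array 3 (-0.47) and without control array 3 (0.41). Without a filter, medians were -0.017 for neuronal bHLH factors, 0.076 for oligodendrocyte, -0.023 for endothelial and 0.023 for progenitor markers and -0.0094 for ion channels; with the stricter filter, -0.020 for excitatory markers and -0.14 for ion channels. The Gapdh covariate gave -0.084 for neuronal bHLH factors, 0.064 for astrocyte and 0.046 for microglia markers. Array weights gave -0.089 for pan-neuronal, -0.12 for endothelial and 0.10 for progenitor markers. Endothelial markers were at -0.014 without a pseudocount, -0.0046 with the higher one and -0.026 with quantile normalization, with or without the block, and progenitor markers at 0.051 with the mean of all probe sets.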

Other observations

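Of 2540 genes with 2 or more tested probe sets, 6 had all of them at an unadjusted p under 0.05 in 1 direction, with no call in the adjusted test beyond those in the report. Plppr4 (log2 differences 1.32 and 2.03), Elavl2 (0.96 and 1.04), Clmp, a cell adhesion gene (0.91 and 1.05), and the ribosomal protein gene Rpl7 (0.50 and 0.95) were higher in the Math2 arrays. Atrn (-0.95 and -0.68) and Kmt2d, a histone methyltransferase (-1.95 and -0.77), were lower. Of the 10 splits of the 6 arrays, 6 gave as many such genes as the real one, with up to 68 in another split. The other 3 splits that part every numbered pair gave 0, 2 and 0.

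Chosen after the result was seen were the tests of Plppr4 by neuronal markers and by its other probe set, and the tests of the interferon list by quantile normalization, estimated correlation and other splits. The 10 splits of 6 arrays, or the 4 that part every numbered pair, are too few for a share under 0.05. Without the block the real grouping called 0 probe sets, as did all 10 of 10 splits. With the block it called 3, as many as in 1 of the 4 splits, itself, and the highest other count was 0. The size rule gave 130 in the real grouping and up to 688 in another, with 6 of 10 as large. Camera called 2 lists, against up to 13 in another split, with 8 of 10 calling as many. The other 3 splits that part every numbered pair gave 48, 66 and 52 probe sets by the size rule and called 0, 3 and 5 lists, and every size count above 130 came from a split that keeps some numbered pairs together. The split of control array 1 with Math2 arrays 1 and 3 from the rest follows the Gapdh 3' to 5' ratio, at 8.14 or more against 6 or less, and gave 3140 probe sets at an unadjusted p under 0.05 and the count of 688, which points to a structure of the samples other than the groups. By the actin 3' to 5' ratio, control array 1 and Math2 arrays 2 and 3 were highest, at 22.7, 17.1 and 18.4. That split gave 157 probe sets at an unadjusted limma p under 0.05 and a size count of 52. The actin and Gapdh ratios thus part the arrays differently, so transcript completeness is not shown to be that structure. With the Gapdh ratio as a covariate, 0 probe sets were called, and the log2 difference of the brighter Plppr4 probe set was 1.98 (limma adjusted p = 0.926).

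The higher signal of Plppr4 in the Math2 arrays had 3 technical readings tested. Intensity-dependent scaling is argued against by the log2 difference of 2.08 with quantile normalization and the block (SE 0.255; limma adjusted p = 0.0047, and 7.84e-05 to 1.00 over all alternatives). A higher share of neurons among the selected cells would raise other neuronal genes by a similar amount, yet the 75th percentile of the pan-neuronal markers was 0.13, below the Plppr4 difference less 2 standard errors, 1.4. This covers the overall share of neurons only, and a shift in the type or maturity of the neurons was not tested. A signal of 1 probe set only stays open: the other probe set was higher too, at 1.32 (SE 0.351), but its control signals lay below every array median, where signal over background is unknown. Regulation of Plppr4 by Math2 stays open as a hypothesis that no test here decides, as do other causes tied to the groups, and the Neurod6 probe set, which may lie outside the transfected sequence, had a log2 difference of 0.021 and was higher in 1 of 3 pairs.

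The interferon response genes were higher as a list, and transfection itself can induce such genes in either group. Intensity-dependent scaling as the whole cause was tested with quantile normalization and the block. Camera at the preset correlation then gave adjusted p = 1.285e-05, against 8.56e-14 to 0.882 over all alternatives. Other splits of the arrays also gave very small p at that correlation, so this test does not decide on scaling. The list's median was 0.24 without and 0.17 with quantile normalization. A contribution of 1 numbered pair stays open: pair medians were 0.776, 0.0978 and 0.149, and the lowest lay within the central 95% of random lists in that pair, which reached 0.193. Genes of the list that move together by chance cannot be told apart from an effect, since camera with an estimated correlation gave p = 0.257. In 5 of 10 splits the list had as small an adjusted p as the real 1.19e-04, and the smallest was 1.92e-16, or 1.83e-05 among the other 3 splits that part every numbered pair, so a difference between samples that is unrelated to Math2 may account for it.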
